A study of Mus musculus with 2 samples.

How the data were processed

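Single-cell RNA sequencing was run on mouse esophageal epithelial cells from 2 genotypes, with 1 library each. Per the series' design text, the control animals carried a floxed Mettl3 gene, with no Cre named, and the knockout animals carried the same floxed gene with a tamoxifen-regulated Cre recombinase under control of Sox2. Mettl3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. Per the labels' protocols, live cells positive for the epithelial surface protein EpCAM were sorted, immune cells were excluded, and libraries were made with 10x Genomics Chromium 3′ chemistry, which counts tags near the 3′ end of transcripts. The sort removes most immune and stromal cells, so shares of cells describe the sorted fraction.

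The deposited matrices hold raw UMI counts per gene and barcode, not normalized. Per the file headers they were made with Cell Ranger 7.2.0, whereas the submitters' processing notes name Cell Ranger 7.1.0, together with Seurat and the build GRCm38 (mm10). The gene annotation is not given in the sources used here. Each matrix lists 32285 genes. Of the gene identifiers, 99.6% were also present in GENCODE vM21, which was used for coordinates on GRCm38 and for transcript sequences. Whether intronic reads were counted is not given in the sources used here. UMIs of near-identical paralogs can be lost or assigned to the wrong copy, so single members of the Sprr2, Lce3, Ces1, Krt6 and Krt14/Krt16/Krt17 groups are uncertain.

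Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs were kept. Scrublet (scanpy 1.11.5, expected rate 0.06) called 3 cells in the library labelled wild type and 4 in the library labelled knockout, which is 0.0742% and 0.0749% of the cells passing. A caller that marks under 0.5% of cells is taken not to have worked, so doublets remain in both libraries. Cells of both libraries were scaled to 10000 UMIs, log-transformed and clustered together on 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden resolution 0.6, without integration. Clusters were named within each library from 14 marker sets fixed before the data were examined, of which 4 describe esophageal epithelial layers. The scoring rule was set after the clusters had been seen. It asked for a mean log2 marker score above 0.3, at least 3 detected markers, fewer than 3 cell cycle genes among the 10 leading genes unless the name was proliferating, and no other epithelial class with more markers among those 10. A cluster whose median depth was under the library median divided by 3, with no marker of its own among those 10, was also left unnamed. Clusters of under 50 cells in a library got no name there. Counted as cell cycle genes were the G1/S and G2/M lists, the proliferating markers and every histone gene of the Hist1h and Hist2h groups. The rule left 2 clusters of the library labelled knockout without a name, with 866 and 175 cells. With stray cells in the other clusters, 19.7% and 0.396% of the cells of the libraries labelled knockout and wild type were unnamed.

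Raw UMIs were summed over all kept cells of a library, and over the cells of each class with at least 50 cells in both libraries. Sums were divided by their total to give CPM (UMIs of a gene per 1000000 UMIs). With no replicates there is no test of the genotype, and no p-value was computed. Each fold is the ratio of CPM in the library labelled knockout to that in the library labelled wild type, or its inverse where stated, with an exact conditional 95% interval. Shares of cells have exact Clopper-Pearson 95% intervals, and CPM values have exact Poisson intervals. All of these cover counting error only. Where a library had 0 UMIs, the fold was computed against 3 UMIs and is a bound. For 31 gene lists fixed before the data were examined, the median log2 fold was taken over members with a CPM of at least 5 in either library. Its interval comes from binomial order statistics over genes, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. These describe the 2 libraries. To compare shares of cells with a UMI, cells were thinned to 2000 UMIs.

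Genes were named by a rule fixed before the data were examined. Among genes with a CPM of at least 20 in either library and at least 100 UMIs over both, leaving out mitochondrial, ribosomal protein and unnamed genes, it took the 10 with the largest fold on each side for the whole library and the basal-like class, and 5 on each side for the other classes. The 2 highest and 2 lowest members of each list and 12 genes fixed in advance could also be named. Any other gene named was chosen after its values were seen.

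TMM factors (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0) were computed in R 4.3.3 for scaling only. The fold and list calculations were tested on simulated counts. For the whole library, the intervals held the true value in 98% of 100 genes raised 2-fold, in 94% of 100 genes lowered to 0.5 and in 95.1% of 8447 unchanged genes. These counts were drawn from the Poisson model that the intervals assume. They check the calculation, not the spread between cells or libraries. For the motif relation in the closing section, DRACH motifs, the sequence context of m6A, were counted on the longest coding transcript of each gene and split at 200 nt from the nearest exon junction. Log2 folds were regressed on motif counts, transcript length, GC content, intron length and mean expression with 2000 bootstrap draws over genes. On simulated folds for the basal-like class, coefficients of 0, -0.3 and 0.3 were recovered with means of -0.00024, -0.297 and 0.295 over 8600 genes, and 37, 38 and 38 of 40 intervals held the true value. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

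Alternatives covered the library scaling, the weight of cells, depth, the expression filter on lists, the cell filters, doublets, clustering and thinning, and 5 further settings were added after seeing the data. Leaving out replicates was not possible with 1 library per group.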

Results

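EpCAM-positive cells of the mouse esophageal epithelium were profiled by single-cell RNA sequencing in 1 library labelled wild type and 1 library labelled Mettl3 knockout. Neither group has a replicate, so no difference below has a replicate check, and each value compares these 2 libraries rather than the genotypes. The library labelled wild type held 4224 barcodes and 120108646 UMIs. Of these barcodes 4038 were kept, with a median of 26103 UMIs and 3983 genes per cell. The library labelled knockout held 5510 barcodes and 99154771 UMIs, and 5334 cells were kept with a median of 16983.5 UMIs and 3623 genes. The median mitochondrial share was 2.12% and 4.99% of UMIs, respectively. Per the series' design text, the comparison addresses changes in cell state during early remodelling of the epithelium.

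Mettl3, the targeted gene, was lower in the library labelled wild type. It had 261 UMIs there (2.18 CPM, 1.92 to 2.46) and 1691 UMIs in the library labelled knockout (17.1 CPM, 16.3 to 18.0), a fold of 7.85 (6.89 to 8.98). The same order held within each class compared, with folds of 4.09 (3.15 to 5.37) in basal-like, 5.15 (3.99 to 6.70) in proliferating-like and 8.50 (6.76 to 10.8) in suprabasal-like cells. After thinning to 2000 UMIs, 23 of 3999 cells (0.575%, 0.365 to 0.862) and 177 of 5319 cells (3.33%, 2.86 to 3.85) had a Mettl3 UMI. Thinning left out 39 and 15 cells, and the unthinned shares were 6.14% and 26.5%. At this depth the log2 fold was 2.56 (1.93 to 3.25) over all cells and 1.07 (0.081 to 2.19) in basal-like cells, where full depth gave 2.03. No class that should lack Mettl3 was available as a background. The gene (ENSMUSG00000022160) lies on chromosome 14 from 52294841 to 52305128 on the minus strand of GRCm38, and its longest coding transcript has 11 exons. The exons between the loxP sites are not given in the sources used here. A 3′ tag outside the deleted part does not check the deletion, so these counts cannot show it. Because Mettl3 runs against the labels, the libraries are named by their labels throughout, and no direction below is assigned to the loss of Mettl3.

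**Figure D1:**
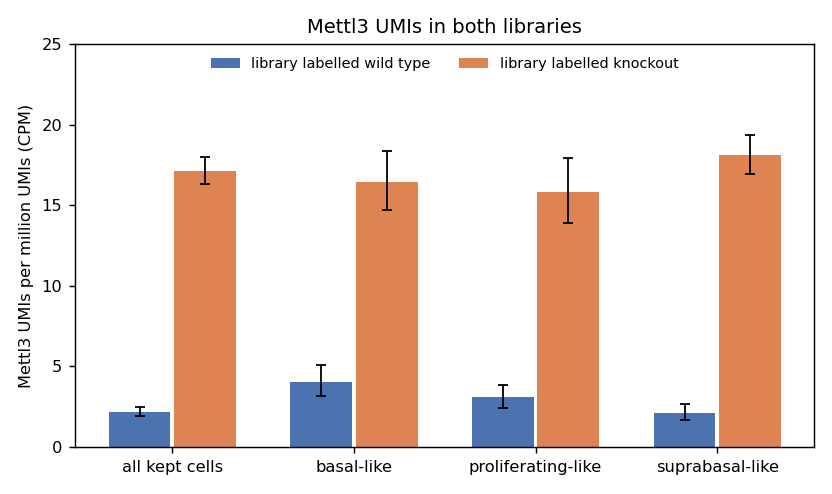
Mettl3 expression (CPM, linear axis) in all kept cells and in 3 classes, for the library labelled wild type and the library labelled knockout. Bars are values of 1 library and lines are exact Poisson 95% intervals, covering counting error only. In each class the library labelled wild type lies lower, from 2.13 CPM in suprabasal-like to 4.03 CPM in basal-like cells, against 15.8 to 18.1 CPM in the other library.

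Of the other members of the m6A machinery, Mettl14, the partner of Mettl3, had 4.18 CPM in the library labelled wild type and 7.98 CPM in the library labelled knockout, a fold of 1.91 (1.71 to 2.14). Rbm15, an adaptor of the writer complex, was 2.83-fold higher in the library labelled wild type (51.8 against 18.3 CPM), and the reader Ythdf2 was 2.09-fold higher there. The demethylase Fto was 3.03-fold higher in the library labelled knockout. Over the 9 measured writer genes the median log2 fold was 0.14 (-0.37 to 0.93), and over the 10 measured readers and erasers 0.24 (-0.49 to 1.03). Both medians took the opposite sign under TMM scaling, at -0.26 and -0.17.

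Over all kept cells, many genes of the cornified envelope, the protein shell of terminally differentiating keratinocytes, were nearly missing from the library labelled knockout, though not all: Evpl was 2.27-fold higher in the library labelled wild type and Casp14 had 11.4 and 10.7 CPM. Sprr2d had 220798 UMIs in the library labelled wild type and 0 in the other, which, counted against 3 UMIs, makes it at least 60707-fold higher there. Lce3a, Sprr2e, Lce3b and Rptn likewise had 0 UMIs in the library labelled knockout and, counted in the same way, were at least 21014-fold, 18766-fold, 12952-fold and 5273-fold higher in the library labelled wild type. Sprr2f had 3754 against 0.273 CPM, a fold of 13729 (9436 to 20833 in the same direction). Il1f6, an interleukin 1 family cytokine, had 3 UMIs in the library labelled knockout and was 31311-fold higher in the library labelled wild type (10714 to 151831). Arg1, which splits arginine to urea and ornithine, had 2 UMIs there and a fold of 6160 (1705 to 50872) in the same direction. Lce3f and Sprr2i had 1 and 5 UMIs there and folds of 16727 (3002 to 660707) and 15859 (6796 to 48845). Of the 10 genes named on this side, 8 lie within 1.06 Mb on chromosome 3, from 92339140 to 93399442 on GRCm38. They are the Sprr2 and Lce3 paralogs above and Rptn, so they are not 8 independent observations of this location. On the other side, genes higher in the library labelled knockout were led by Igfbp5, a binding protein of insulin-like growth factors (26.5 against 0.0585 CPM, 453-fold, 220 to 1128). Il1r2, the decoy receptor of interleukin 1, was 130-fold higher (109 to 156), and Arhgap25, Tsc22d3, Cyp2f2, Tenm2, Rbms3, Dlk2, Smoc2 and Ces1d were 95.3-fold to 19.2-fold higher.

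The keratins of the basal layer did not move together. Krt15 was 16.1-fold higher in the library labelled knockout (6181 against 384 CPM) and Krt5 2.89-fold higher (2835 against 980 CPM), whereas Krt14 was 2.72-fold higher in the library labelled wild type (9469 against 3482 CPM). Trp63 and Sox2, transcription factors of basal cells, were 4.64-fold and 3.12-fold higher in the library labelled knockout. The Cre allele is tied to Sox2 by the series' design text, and its effect on Sox2 counts cannot be resolved here. The suprabasal keratins Krt4 and Krt13 were 2.78-fold and 2.15-fold higher in the library labelled wild type. Epcam, the gene of the sorting marker, was 1.81-fold higher in the library labelled knockout, and Ptprc, which marks immune cells, had 0 UMIs in both, where 3 UMIs are the limit that a count of 0 allows.

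Measured by gene lists, the difference was broad. The median log2 fold over 9274 genes was 0.36, and TMM and DESeq2 scaling moved every log2 fold by -0.41 and -0.45, so list medians are read against that shift. The basal progenitor and basement membrane adhesion list was higher in the library labelled knockout, with 17 of 18 measured members above 0 and a median of 1.70 (1.49 to 2.63). Dst and Col17a1, which anchor basal cells to the basement membrane, were 8.90-fold and 6.21-fold higher there (Col17a1 was chosen after its values were seen). Of 20 early suprabasal differentiation genes, 20 were below 0, with a median of -1.41 (-2.72 to -1.06), and Serpinb2 was 33.4-fold higher in the library labelled wild type. The cornified envelope list had 29 of 29 members below 0 and a median of -8.75 (-12.02 to -3.95). The list of wound and hyperproliferation keratinocyte genes had 13 of 14 members below 0 and a median of -6.95 (-11.09 to -3.12). Krt16, a keratin induced in wounded epidermis, had 15097 against 6.51 CPM, and S100a8, an alarmin, had 458 against 0.162 CPM. The exception was Plau, at 1.80 against 5.68 CPM. These 4 lists kept their sign under both scalings.

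Targets of p53 were mostly lower in the library labelled knockout, with 23 of 25 members below 0 and a median of -1.26 (-1.82 to -0.83). Gdf15 was 61.4-fold and Ddit4l 22.1-fold higher in the library labelled wild type, and Cdkn1a, the inhibitor of cyclin-dependent kinases, 7.21-fold higher (chosen after its whole-library values were seen). Sesn1 went the other way, 8.71-fold higher in the library labelled knockout. Inflammatory cytokines and NF-kB targets had a median of -1.71 (-5.29 to -0.99), led by Il33 at 142 against 0.354 CPM. Genes of EGFR and ERK signalling had a median of -1.55 (-4.32 to -0.28), led by the EGFR ligands Ereg (95.9 against 0.0911 CPM) and Areg (84.3 against 0.182 CPM). Both ligands are also members of the wound list, and within each class compared the EGFR and ERK interval spanned 0 before scaling. Desmosome and cell junction genes stood at -1.02 (-4.43 to -0.46), and cholesterol synthesis genes at -0.69 (-0.95 to -0.39). Interferon-stimulated genes had a median of -1.01, with an interval from -4.19 to 0.71, since Oasl1, with 1 UMI in the library labelled knockout, and Isg15 were 3502-fold (628 to 138364) and 29.4-fold higher in the library labelled wild type while 5 of 12 members were above 0. Differentiation transcription factors had a median of -1.31 (-2.19 to 0.24), but -1.72 with TMM and -1.76 with DESeq2 scaling, with intervals below 0. Before scaling, their interval lay below 0 in basal-like (-4.18 to -0.036) and proliferating-like cells (-3.32 to -0.019). In suprabasal-like cells it spanned 0 (-1.77 to 0.13).

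Higher in the library labelled knockout were cytosolic ribosomal protein genes, with 44 of 44 members above 0 and a median of 0.71 (0.62 to 0.80). Mitochondrially encoded genes had 13 of 13 above 0 and a median of 1.09 (0.79 to 1.69), beside the higher mitochondrial share of that library. Nuclear-encoded oxidative phosphorylation genes stood at 0.64 (0.47 to 0.87), and the 3 nuclear-retained RNAs at 1.44. Malat1 was 2.71-fold higher there. Relative to the median of all genes these 4 lists stood at 0.35, 0.73, 0.28 and 1.08. The 7 measured genes of epithelial-mesenchymal transition had a median of 1.99 (0.44 to 2.57), with Sparc 5.96-fold and Snai2 5.57-fold higher. The fibroblast marker Dcn also went this way, at 0.0167 against 7.26 CPM (2 UMIs in the library labelled wild type), and the source of these UMIs was not tested. Of the 31 lists, 7 had intervals above 0 and 8 below 0, and 6 and 8 of these kept their sign under both scalings. The exception was the G1/S list, at 0.22 (0.04 to 0.53) and at -0.19 with TMM factors.

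The other signalling and stress lists had whole-library intervals that spanned 0 before scaling. Notch pathway genes stood at 0.69 (-0.60 to 2.38), with Lfng and the ligand Jag2 21.8-fold and 5.22-fold higher in the library labelled knockout. Wnt and beta-catenin targets stood at 1.01 (-0.073 to 2.18), led by Dkk3 (10.3-fold), YAP/TAZ targets at 0.68 (-0.84 to 1.78), and the TGF-beta and BMP response at 0.72 (-0.64 to 2.07). In the last, Tgfbi was 5.27-fold higher in the library labelled knockout and Id1 15.5-fold higher in the library labelled wild type. The integrated stress and unfolded protein response stood at -0.14 (-0.70 to 0.22), but at -0.55 with TMM and -0.60 with DESeq2 scaling with intervals below 0, and apoptosis and lytic death genes at -0.16 (-0.71 to 0.82). NRF2 targets stood at 0.21 (-0.59 to 1.08), glycolysis and hypoxia genes at 0.084 (-0.18 to 0.76), MHC class I presentation genes at 0.073 (-1.43 to 0.70) and immediate early genes at 0.0018 (-1.19 to 0.41). These last 4 took a negative sign under TMM scaling, at -0.20, -0.32, -0.33 and -0.41, and the interval of the immediate early genes lay below 0 with DESeq2 scaling, at -0.45. The 4 measured sex-chromosome genes, Ddx3y, Eif2s3y, Kdm5d and Uty, are all Y-linked and had UMIs in both libraries. Their median was 0.996, with 3 above 0. Ddx3y went the other way, at a log2 fold of -0.40, with 3678 and 2301 UMIs in the libraries labelled wild type and knockout.

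Markers of other cell types were low in both libraries. Summed over each marker set, immune markers had 5.56 CPM in the library labelled wild type and 1.03 CPM in the library labelled knockout, fibroblast markers 0.0501 and 7.30 CPM (7.26 CPM of the latter from Dcn alone), endothelial markers 5.66 and 2.79 CPM, and muscle markers 3.38 and 3.75 CPM. Glial markers had 0.251 and 1.16 CPM, columnar markers 8.25 and 1.18 CPM, melanocyte markers 1.24 and 0.395 CPM, erythroid markers 0.835 and 0.435 CPM, and thyroid markers 0.0585 and 0.0405 CPM. The airway set was made up almost wholly of Tppp3, at 84.5 and 215 CPM. No cluster was named for any of these types.

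Clustering gave 10 clusters, and only 25 of 9372 cells lay in a cluster made up mainly of the other library. In the library labelled wild type, cluster 0 was basal-like (846 cells, 21.0%, 19.7 to 22.2), cluster 3 proliferating-like (1003 cells, 24.8%, 23.5 to 26.2), cluster 1 suprabasal-like (1179 cells, 29.2%, 27.8 to 30.6) and cluster 2 superficial-like (994 cells, 24.6%, 23.3 to 26.0). In the library labelled knockout, cluster 6 was basal-like (1382 cells, 25.9%, 24.7 to 27.1), cluster 8 proliferating-like (673 cells, 12.6%, 11.7 to 13.5) and clusters 4 and 5 suprabasal-like (2229 cells, 41.8%, 40.5 to 43.1). Superficial-like cells numbered 0 of 5334 there, where 3 cells, the limit taken for a count of 0, make 0.0562% and the exact interval reaches 0.0691%. That limit covers counting only, and the 0 follows from the naming rule. Cluster 4, named suprabasal-like at a score of 2.5, also scored 1.19 on the superficial set, with 8 of its markers detected. Clusters 7 and 9, with 866 and 175 cells, had no name, and 5 and 8 of their 10 leading genes counted as cell cycle genes. They scored 0.419 and 0.331 on the basal set and -0.387 and -0.336 on the proliferating set. In cluster 7 the genes counted included the histone genes Hist1h1c, Hist1h2bc and Hist1h4i. Without the histone genes the rule would have named cluster 7 basal-like. Because each class is held by different clusters in the 2 libraries and the genes that define them differ, no direction is read from these shares.

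Within basal-like cells (cluster 0 with 846 cells against cluster 6 with 1382 cells), many wound and cornified envelope genes were again nearly missing from the library labelled knockout. Others were not: Evpl, Sprr2a3 and Stfa3 were 2.50-fold, 2.21-fold and 2.07-fold higher in the library labelled wild type, and Tnc was higher in the library labelled knockout, at a log2 fold of 2.30. Krt6b had 1140 CPM against 1 UMI, a fold of 22591 (4054 to 892354 in the same direction), and Krt16 had 2941 against 1.01 CPM, a fold of 2914. Slpi, a secreted protease inhibitor, had 712 CPM against 2 UMIs, a fold of 7052 (1952 to 58236). Sprr1b and S100a9 had 0 UMIs in the library labelled knockout and, counted against 3 UMIs, were at least 2315-fold and 568-fold higher in the library labelled wild type. Cnfn, with 1 UMI in the library labelled knockout, was 1094-fold higher in the other (196 to 43256), and Areg, with 3 UMIs, 586-fold higher (200 to 2845). Sprr1a, Crabp2 and Ly6g6c were 901-fold to 619-fold higher there. The genes with the largest folds toward the library labelled knockout were Igfbp5 (31.0 against 0.173 CPM, 180-fold, 61.2 to 873), Arhgap25 (55.3-fold), Il1r2 (50.6-fold) and Dlk2 (41.3-fold). Klf15, Sema3d, Lfng, Tsc22d3, H19 and Ackr3 were 35.8-fold to 20.6-fold higher.

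The keratins in basal-like cells had the directions of the whole library, though not the sizes. Krt15 was 13.8-fold higher in the library labelled knockout (10417 against 755 CPM), Krt5 2.03-fold and Trp63 3.43-fold higher, and Sox2 2.75-fold higher. Krt14 was 1.36-fold (8906 against 6557 CPM), Krt4 11.1-fold and Krt13 3.10-fold higher in the library labelled wild type. The suprabasal keratin Krt13 had 14203 CPM in the library labelled wild type, above Krt14, Krt5 (2083 CPM) and Krt15 there. In the library labelled knockout it had 4577 CPM, below Krt15. The 2 basal-like clusters thus differ in keratin makeup, and folds between them do not compare matched basal cells. The cause was not tested. The basal progenitor list, of whose 20 genes 10 also served to name the class within each library, had 18 of 20 members above 0 and a median of 1.57 (1.20 to 1.94). The early suprabasal, cornified and wound lists stood at -3.43 (-4.37 to -1.52), -5.89 (-7.49 to -2.27) and -5.91 (-9.20 to -1.68), with 19 of 19, 19 of 19 and 12 of 13 members below 0 (10 of the 20 early suprabasal and 14 of the 36 cornified genes also served to name the suprabasal-like and superficial-like classes). Targets of p53 had 25 of 26 members below 0 and a median of -1.84 (-2.90 to -1.26). Cholesterol synthesis genes had 18 of 19 members below 0 and a median of -2.33 (-2.74 to -1.08), with Mvd at 10.3 against 0.908 CPM and Sqle at 28.5 against 2.88 CPM. Ribosomal protein genes stood at 0.37 (0.21 to 0.45) beside a median of 0.13 over all genes of this class. G2/M genes had 13 of 16 members below 0 and a median of -0.80 (-2.06 to -0.19), which became -0.14 at a mitochondrial share of at most 10%, -0.15 with at least 2000 UMIs per cell, and 1.54 (0.70 to 2.11) when clusters 7 and 9 were added to the class, a setting chosen after seeing the data. G1/S genes stood at -0.52 (-0.71 to -0.0079), and became 0.12 under the same setting, 0.56 with at least 2000 UMIs per cell and 0.23 with called doublets kept, so no direction is read from them. In this class TMM and DESeq2 scaling moved every log2 fold by -0.15 and -0.18, and the interferon list alone took the opposite sign under them.

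**Figure D2:**
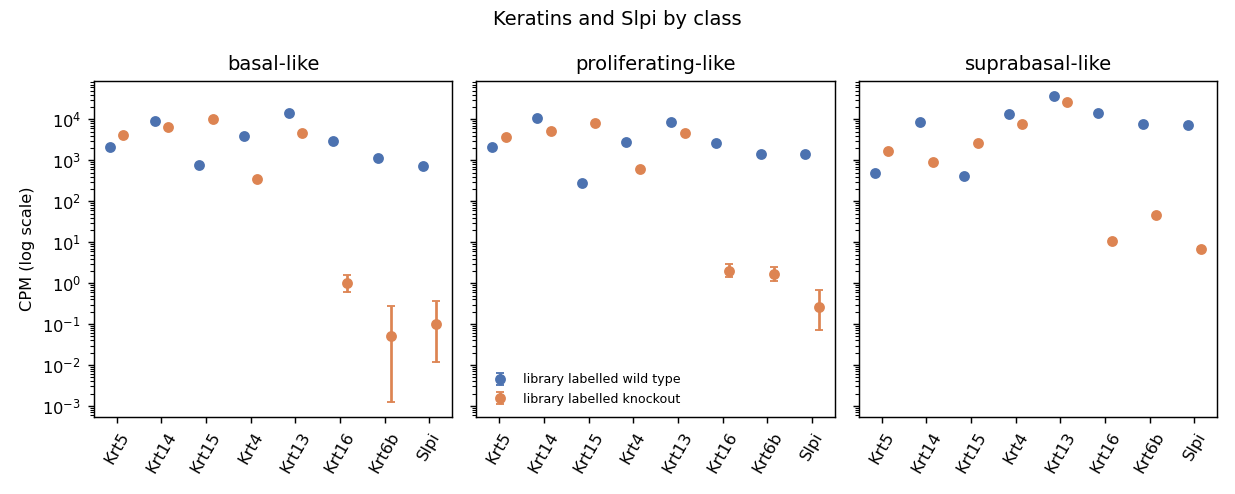
CPM (log axis) of 7 keratins and Slpi in 3 classes of the library labelled wild type and the library labelled knockout. Points are values of 1 library with exact Poisson 95% intervals, covering counting error only, most of them smaller than the point. Krt16, Krt6b and Slpi lie between 712 and 14600 CPM in the library labelled wild type and between 0.0505 and 47.0 CPM in the other, while Krt15 and Krt5 lie higher in the library labelled knockout in each class.

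Within proliferating-like cells (cluster 3 with 1003 cells against cluster 8 with 673 cells), genes of the G2 and M phases were higher in the library labelled knockout. All 22 measured members lay above 0, with a median of 1.52 (1.32 to 1.90). Clusters 7 and 9, kept unnamed by the count of cell cycle and histone genes, are left out of this class. With them joined to it, a setting chosen after seeing the data, the median was 0.84 (0.36 to 1.18). Nusap1, a spindle protein, was 9.02-fold higher (8.41 to 9.68), Top2a 5.19-fold and Mki67 3.74-fold higher, whereas Birc5 was 1.22-fold higher. Of the 22 genes, 8 also served to name the class. G1/S genes stood at 0.23 (-0.04 to 0.77). Slpi, S100a9, Sprr2f, Sprr1b and Krt16 were the genes with the largest folds toward the library labelled wild type, with Krt16 at 2619 against 2.03 CPM. Igfbp5, Il1r2, Cyp4b1, Arhgap25 and Ces1d had the largest folds toward the library labelled knockout, with Il1r2 at 87.9 against 0.449 CPM. Here the scaling shifts were -0.14 and -0.17. Targets of p53 stood at -1.66 (-2.14 to -0.70) and the wound list at -6.35 (-9.74 to -3.80).

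Within suprabasal-like cells (cluster 1 with 1179 cells against clusters 4 and 5 with 2229 cells), Il1f6, Sprr2d, Sprr2f, Sprr2e and Sprr2i had the largest folds toward the library labelled wild type, with Sprr2f at 1036 against 0.186 CPM. Il1r2 (105 against 0.710 CPM, 148-fold), Cyp2f2 (24.4-fold), Ces1d (23.8-fold), Mir205hg (23.8-fold) and Dst (22.3-fold) had the largest folds toward the library labelled knockout. Cyp2f2 and Ces1d were also among the 10 leading genes of cluster 5 within its own library. Cluster 5 scored 0.375 on the suprabasal set, against 2.5 for cluster 4, so pooling the 2 clusters bears on these folds. The cornified list stood at -5.05 (-7.91 to -1.71), the wound list at -6.53 (-9.85 to -1.17) and p53 targets at -1.31 (-1.60 to -0.84). The scaling shifts in this class were -0.38 and -0.41, and these 3 lists kept their sign. Krt14 was 9.71-fold higher in the library labelled wild type. Krt4, at 13150 against 7907 CPM, and Krt5, at 492 against 1687 CPM, took the opposite order, with log2 folds of 0.037 and -0.037, when each library was limited to its cluster with the highest marker score, a setting added after seeing the data.

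**Figure D3:**
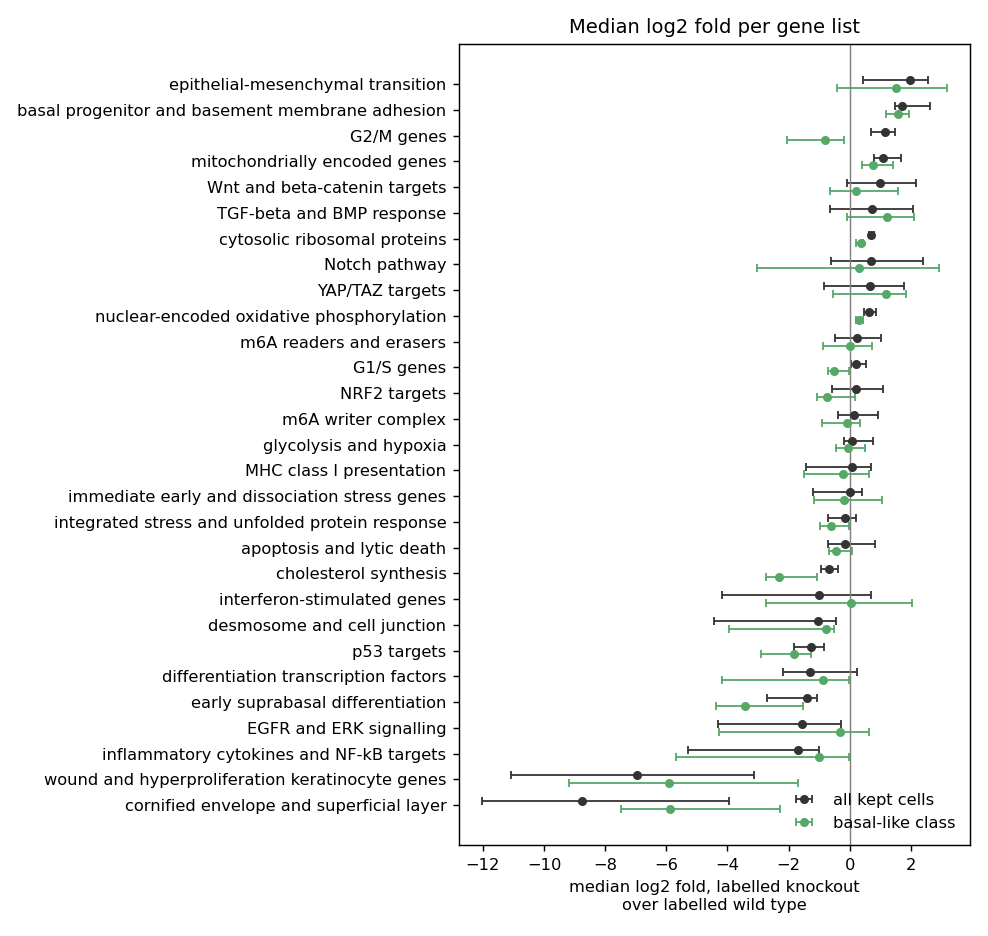
Median log2 fold of the library labelled knockout over the library labelled wild type for 29 gene lists with an interval, in all kept cells and in basal-like cells. Points are medians over measured members and lines are order-statistic 95% intervals over genes. Cornified and wound lists lie lowest, at -8.75 and -6.95 in all kept cells. G2/M genes lie at 1.15 in all kept cells and at -0.80 in basal-like cells, and the G1/S point for all kept cells crosses 0 under TMM scaling.

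Cycling was measured on thinned cells, and its order depended on the measure and on depth. An Mki67 or Top2a UMI was found in 541 of 3999 cells of the library labelled wild type (13.5%, 12.5 to 14.6) and in 1037 of 5319 cells of the library labelled knockout (19.5%, 18.4 to 20.6). Without thinning the shares were 38.7% and 38.9%. In superficial-like cells of the library labelled wild type, which should not divide, the share was 0.911%, or 10.4% without thinning at a median depth of 34634 UMIs. At least 3 UMIs of the G2/M list were found in 26.0% and 22.8% of cells, the opposite order, but in 17.9% and 18.0% after thinning to 1000 UMIs and in 64.0% and 75.5% without thinning. Within proliferating-like cells the shares with an Mki67 or Top2a UMI were 44.9% (41.8 to 48.1) and 92.8% (90.6 to 94.7), or 44.9% and 54.0% (51.6 to 56.4) with clusters 7 and 9 joined. The shares with at least 3 G2/M UMIs were 86.9% and 99.7%, or 86.9% and 66.1%, the opposite order, with those clusters joined. The G2/M list stood at 1.15 (0.69 to 1.49) over all kept cells, with 21 of 22 members above 0, and Mki67 was 2.81-fold higher in the library labelled knockout.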

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

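Chosen only after the results were seen were the settings that join 2 clusters to the basal-like or the proliferating-like class, the test that leaves 50 genes out of the library totals, and the use of the fold's own intervals in the depth test of Mettl3. The other tests were set down after the whole-library values had been seen but before the value each measures.

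Genes of the G2 and M phases went opposite ways in different cell classes, which is why they are taken up here. In proliferating-like cells the median log2 fold of the library labelled knockout over the library labelled wild type was 1.52 (1.32 to 1.90), with Nusap1 and Top2a 9.02-fold and 5.19-fold higher. In basal-like cells it was -0.80 (-2.06 to -0.19) over 16 genes and in suprabasal-like cells -1.25 (-3.30 to -0.087) over 10 genes. The difference between the classes was not tested, since each class has 1 library per group. Clusters 7 and 9 were kept unnamed by the count of cell cycle and histone genes. With them joined to the basal-like class its median was 1.54, and with them joined to the proliferating-like class that median was 0.84. At a mitochondrial share of at most 10% the basal-like and suprabasal-like medians were -0.14 (-1.51 to 0.29) and 0.022 (-2.45 to 0.49), and with at least 2000 UMIs per cell the basal-like median was -0.15 (-1.19 to 0.16). These last 3 intervals span 0, so the opposite directions depend on the cell filter. The naming rule also kept clusters 7 and 9 out of the basal-like class, in the library labelled knockout only. That lowers its basal-like G2/M median, so no direction is read from this contrast, and its cause was not tested.

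Mettl3 had 2.18 CPM in the library labelled wild type and 17.1 CPM in the library labelled knockout, against the labels. Different shares of cell classes are argued against at full depth, since the lowest fold within a class was 4.09 (3.15 to 5.37), in basal-like cells. After thinning to 2000 UMIs the log2 fold there was 1.07 (0.081 to 2.19), and its interval no longer clears the bound set for this test. The tables argue against counting noise or depth, since the fold lay at percentile 98.8 (97.4 to 99.6) of 500 like-expressed genes, which clears the bound set beforehand only without its interval, and the whole-library log2 fold stayed at 2.56 (1.93 to 3.25) after thinning. An exchange of the 2 labels is a candidate explanation: it predicts that transcripts with more DRACH motifs far from exon junctions, where METTL3 writes m6A, are lower in the library labelled knockout, and the coefficient in basal-like cells was -0.207 (-0.260 to -0.155), against -0.0070 (-0.055 to 0.043) for motifs near junctions. The distal coefficient holds at fixed transcript length, whose own coefficient in that fit was 0.344 (0.283 to 0.402). Lower expression of motif-rich transcripts without that adjustment is not shown. The exchange stays a hypothesis, because motif counts are not measurements of m6A and other effects that follow exon architecture were not tested. A 3′ tag outside the deleted exons would also be counted in a knockout.

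Many cornified and wound genes, among them Sprr2d and Krt16, were nearly missing from the library labelled knockout. Had superficial-like cells alone been missing, with the other classes alike, the wound list in basal-like cells would differ little. It stood at -5.91 (-9.20 to -1.68). Free RNA of the superficial-like cells could lower this median in the same way. The median therefore argues against that explanation only where such free RNA is set aside, which was tested for Krt16 alone. For Krt16 in basal-like cells of the library labelled wild type, free RNA of superficial-like cells is argued against as the main source. There the UMI ratio of Krt16 to Lor was 17.7 times (16.3 to 19.3) that of superficial-like cells (93.0 against 5.25). The test covers Krt16 alone, so for the cornified and other wound genes free RNA of superficial-like cells stays open. Free RNA of suprabasal-like cells, where the ratio of Krt16 to Lor was 116, stays open, as do doublets, since the doublet caller did not work. The genotype, the animal and the handling of each library also stay open, and no biological explanation was tested.

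Ribosomal protein genes (median log2 fold 0.71) and mitochondrially encoded genes (1.09) were higher in the library labelled knockout. For the ribosomal protein genes, a few genes taking most of the counts are argued against, since the median was 0.63 (0.54 to 0.72) with the 50 genes of most UMIs left out of the totals. Different shares of cell classes are argued against by the lowest median within a class, 0.37 (0.21 to 0.45) in basal-like cells, but at 0.22 (0.055 to 0.29) with TMM and 0.19 (0.031 to 0.27) with DESeq2 scaling this test no longer clears its bound. A wider difference in composition stays open, since the whole-library median was 0.30 with TMM and 0.26 with DESeq2 scaling. For the mitochondrially encoded genes cell quality stays open and was not tested, and no biological explanation was tested.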

How the results depend on the processing

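Added after seeing the data were 5 of the 24 settings: removing the highest 4% of doublet scores, joining clusters 7 and 9 to the basal-like or to the proliferating-like class, limiting the suprabasal-like class to 1 cluster per library, and leaving 50 genes out of the totals. The lower expression of early suprabasal, cornified, wound and p53 genes in the library labelled knockout kept its direction, and stayed inside its interval, under each setting with a value, over all cells and in basal-like cells. The cornified median ranged from -9.20 to -7.36 over all cells and from -7.20 to -3.37 in basal-like cells, the wound median from -8.85 to -4.30 and from -8.90 to -3.86, and the p53 median from -1.71 to -1.24 and from -2.14 to -1.66. Mettl3 stayed lower in the library labelled wild type (log2 fold 2.52 to 2.98 over all cells, 1.07 to 2.31 in basal-like cells). Of 1326 log2 folds of other genes under alternatives, 781 stayed inside their interval and 7 with an interval off 0 took the opposite sign, and of 1674 medians of other lists 1496 and 8 did so. Keeping epithelial clusters only removed no cell and gives no value. No paired analysis was possible because each group has 1 library, and no library could be left out.

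In what follows, all values are on the log2 scale, toward the library labelled knockout where positive, and except for the scalings the cause was not tested. TMM and DESeq2 scaling, which shift every fold alike, gave -0.19 and -0.23 for G1/S genes (otherwise 0.22), 1.29 and 1.25 for basal progenitor genes (1.70) and 2.57 and 2.52 for Mettl3 (2.97). The mean over cells gave -0.075 for G1/S genes and 2.74 for Mettl3, and thinning gave -0.095 and 2.56, with 1.07 for Mettl3 in basal-like cells (2.03) and 0.037 for Mki67 in suprabasal-like cells (-0.65). Shares of basal-like, proliferating-like and suprabasal-like cells (0.31, -0.98 and 0.52) moved under many settings. Leiden resolution 0.3 gave a proliferating share of -1.34, and resolution 1.0 gave shares of 0.85, -0.55 and 0.38 and 0.084 for suprabasal Mki67. Centring genes gave basal and proliferating shares of 0.087 and -0.73 and basal progenitor genes at 2.23 in basal-like cells (1.57). With 3000 variable genes the basal and suprabasal shares were 1.33 and 0.23 and basal progenitor genes 1.06. Keeping the 7 called doublets gave basal and proliferating shares of -0.38 and -0.47, with basal progenitor genes at 2.31 and G1/S genes at 0.23 in basal-like cells (-0.52). Removing the highest 4% of doublet scores gave shares of -0.021 and -0.78 and basal progenitor genes at 2.15. A mitochondrial limit of 10% gave shares of 0.53, -0.42 and 0.67, basal G2/M genes at -0.14 (-0.80), suprabasal G2/M genes at 0.022 (-1.25) and suprabasal Mki67 at 0.40. A limit of 25% gave basal and suprabasal shares of 0.77 and 0.41 and Mki67 at 0.12. At least 2000 UMIs per cell gave shares of 1.41 and 0.17, basal progenitor, G1/S and G2/M genes in basal-like cells at 1.14, 0.56 and -0.15, and suprabasal Mki67 at 0.034. At least 500 UMIs and 300 genes gave shares of 0.64, -0.72 and -0.56, and 3.40 for the share with a Mettl3 UMI (2.53). Joining clusters 7 and 9 to the basal-like class gave a share of 1.12, G1/S genes at 0.12 and G2/M genes at 1.54, and joining them to the proliferating-like class gave a share of 0.37. Limiting the suprabasal-like class gave 0.037 for Krt4 (-0.73) and -0.037 for Krt5 (1.78). Depth limits the cycling measures: the share with an Mki67 or Top2a UMI (0.53) was 0.76, 0.31 and 0.0086, and the share with at least 3 G2/M UMIs (-0.19) was 0.0075, -0.0070 and 0.24, at 1000 UMIs, at 4000 UMIs and without thinning.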

Other observations

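No test was run for this part, and where a gene is not among the 2 highest or lowest of its list in the class named, it was chosen after its values were seen.

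Cholesterol synthesis genes had a median log2 fold of -2.33 (-2.74 to -1.08) in basal-like, -1.0 (-1.87 to -0.69) in proliferating-like and -0.17 (-0.47 to 0.10) in suprabasal-like cells. With TMM and DESeq2 scaling these medians were -2.48 and -2.50, -1.14 and -1.17, and -0.54 and -0.58, respectively. Mvd and Sqle were 11.3-fold (6.97 to 19.6) and 9.90-fold (7.51 to 13.3) higher in the library labelled wild type in basal-like cells, 6.47-fold and 5.79-fold higher there in proliferating-like cells, and 1.98-fold and 1.35-fold higher there in suprabasal-like cells. Hmgcs1 went the other way, 1.85-fold higher in the library labelled knockout in basal-like cells. The difference between the classes was not tested.

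The integrated stress and unfolded protein response list had members going both ways in basal-like cells. Slc7a11, the cystine transporter, had 1010 and 7 UMIs in the libraries labelled wild type and knockout, a fold of 164 (79.5 to 410), and Trib3 had 106 and 1 UMIs, a fold of 121 (21.2 to 4816). In proliferating-like cells Slc7a11 was 96.1-fold higher in the library labelled wild type, and Trib3 had 238 and 4 UMIs. Vldlr and Ppp1r15a were 5.41-fold and 2.35-fold higher in the library labelled knockout in basal-like cells, and 7 of 26 members lay above 0, at a median of -0.61 (-0.97 to -0.010). Of the YAP/TAZ targets there, Ccn2 had 1 and 145 UMIs, 127-fold (22.5 to 5060) higher in the library labelled knockout, and Ccn1 was 8.96-fold higher, at a list median of 1.19 whose interval spanned 0.

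Members of the Notch, BMP and NRF2 lists moved apart over all kept cells. Lfng and Jag2 were higher in the library labelled knockout, while the Notch target Nrarp was 2.57-fold higher in the library labelled wild type. Id2 was 5.04-fold higher in the library labelled knockout and Id1 15.5-fold higher in the library labelled wild type. Gstm1 and Hmox1, both NRF2 targets, were 6.17-fold higher in the library labelled knockout and 6.45-fold higher in the library labelled wild type.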
